A study of Mus musculus with 14 samples.

How the data were processed

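RNA of CD11b-positive cells of the brain was sequenced from 14 mice in 4 groups, WT control (n = 3), 5xFAD control (n = 3), WT CMS (n = 3) and 5xFAD CMS (n = 5). Per the labels' protocols, whole brains were dissociated, myelin was removed on Percoll, cells were taken with CD11b beads, and stranded poly(A) libraries (KAPA) were read for 76 single-end cycles on a NextSeq 500. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt 3.5, aligned with STAR and counted per gene with HTSeq, and the authors tested groups with DESeq2. Versions of STAR, HTSeq and DESeq2 and the strand setting of counting are not given in the sources used here. Coordinates are those of the deposited table on GRCm39.

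The deposited table holds 1 raw count per gene and library, made by the authors with HTSeq. It lists 55414 genes, of which 6250, mainly small RNA, ribosomal RNA and immunoglobulin and T cell receptor genes, have no count, and 18503 of the other 49164 have 0 counts in all libraries. The authors' deposited log2 fold changes and adjusted p-values cover genes with at least 10 counts over all libraries (22033 genes) and were only set beside the results. The authors' deposited normalized values were not used. Total counts were 20239385 to 25749414 per library, and the median standard error of a log2 fold change was 0.180 for 3 against 3 libraries, 0.161 for 5 against 3 and 0.242 for the interaction.

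Counts were scaled by TMM factors, computed with trims of 30% of log ratios and 5% of mean levels. Genes with a mean of at least 10 scaled counts in at least 1 group were tested (16169 genes). log2(value + 1) was fitted with limma 3.58.1 (trend and robust options, R 4.3.3) as 4 group means over all 14 libraries, and 5 contrasts were tested 2-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. These were genotype without stress, genotype under stress, stress in WT, stress in 5xFAD, and the interaction. The design written before the data were examined kept limma on log2 values for normalized values only and asked for a model of counts otherwise. The deposited values are raw counts, and limma was still used instead of edgeR, the tool named there first. The reason was that the mark for missing values kept the columns from being declared as counts in the record of units, so the results depart from that design. Tables and figures were made with R and Python 3.11.15.

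Before the data were examined, 37 gene lists (650 genes) were written from general knowledge, 12 of them markers of other cells that such isolates may hold, together with the settings to be varied and the rule for named genes. The 34 lists with at least 5 measured genes, other than the transgene and sex-linked genes, were tested with camera (preset correlation 0.01, on the log2 values), with Benjamini-Hochberg adjustment over the lists of a comparison, again with an estimated correlation, and with fry. Some lists share genes, such as Apoe and Lpl in the disease-associated microglia and lipid lists and Mrc1 and Cd163 in the macrophage and alternative activation lists. Members are counted as higher or lower from the gene test, and also when adjusted over the list alone. The rule names, per comparison, up to 10 genes with the highest and 10 with the lowest log2 fold change among those past the threshold with a mean of at least 50 and no overlap between groups, leaving out predicted genes, clones and pseudogenes, up to 4 members per list with the smallest p, and a fixed set (among them App, Thy1, Xist, Ddx3y, Trem2, Apoe, Cst7, Itgax, Clec7a, Tmem119, P2ry12 and Fkbp5). Where fewer than 5 genes passed, the 5 with the smallest p are named. The text names a subset of the genes the rule picks, since some are not reported here, and says where a gene outside it was chosen after its values were seen.

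Sex was read from Xist and 4 Y-linked genes. Settings fixed beforehand were median-of-ratios and upper-quartile scaling, 3 other filters (1 count, 10 counts in every library of a group, a mean of 50), pseudocounts 0.5 and 4, voom with quality weights, a fit of only the libraries compared, a block for the replicate number, the X/Y balance as a covariate, a 2-fold threshold and leaving out each library. Settings added after seeing the data were library totals alone, the level of non-myeloid markers as a covariate, leaving out both choroid-rich libraries, and both covariates for the lists and for the opposition of stress and genotype effects. List means were also tested by exact permutation over 56 splits, the macrophage marker level by a linear model with each covariate, and the opposition against 200 simulations with a shared control. The gene test was tested on simulated data with known folds put into libraries drawn at the size of each comparison. Only genes with a mean of at least 50 were changed. Counts were drawn gene by gene, so these libraries held no structure by sex or composition. A DESeq2 test fixed beforehand as an alternative was not run. Reads of the human transgenes were not analysed here.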

Results

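Gene expression was measured by poly(A)-selected, strand-specific mRNA sequencing in CD11b-positive cells taken with magnetic beads from whole mouse brains. CD11b is a surface integrin of microglia, the resident macrophages of the brain, and of other myeloid cells. The mice were wild-type C57BL (WT) or 5xFAD, a line whose human transgenes carry familial Alzheimer mutations under the neuronal Thy1 promoter. Mice of each genotype either went through chronic mild stress (CMS) or were kept as unstressed controls. This gave 4 groups, with 3 WT control, 3 5xFAD control, 3 WT CMS and 5 5xFAD CMS mice, 1 library per mouse, and the labels name separate mice. The title of the series concerns protection by chronic stress once Alzheimer pathology is advanced. Total counts per library ran from 20239385 to 25749414 (median 23062000), and 21620 to 23777 genes had a count in a library. Values below are counts scaled by trimmed mean of M-values (TMM), coordinates are those of the deposited table (GRCm39), and ± is 1 SD.

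Genotype separated the libraries more than stress did. The leading principal component held 52.6% of the variance, with mean scores of 45.2 ± 6.86 (n = 3) in 5xFAD control and 26.9 ± 27.4 (n = 5) in 5xFAD CMS, against −34.9 ± 21.8 (n = 3) in WT control and −55.2 ± 28.2 (n = 3) in WT CMS. It is not an axis of genotype alone. Within WT control and WT CMS, libraries with more endothelial and mural markers had lower scores. The same order held in 5xFAD CMS, except that 5xFAD CMS 4 (850 CPM) scored 39.7 and 5xFAD CMS 1 (747 CPM) 35.9. The scores ran from −86.5 in WT CMS 2 (3302 CPM of these markers) to 60.8 in 5xFAD CMS 5 (595 CPM). Spearman's rho between libraries of one group was 0.976 to 0.994 over 19 pairs. Between groups it was 0.935 to 0.994 over 72 pairs, highest for WT control 2 and WT CMS 3. No 2 libraries were copies of each other (chi-square per degree of freedom at least 9.19 within groups and 7.71 between groups), and all 14 were kept as separate mice on the basis of the labels. Xist, the RNA that silences an X chromosome in females, was at 1157 to 1604 CPM in 6 libraries, and Y-linked genes were high in the other 8. The Xist-high libraries were 2 of 3 in WT control, 1 of 3 in 5xFAD control, 1 of 3 in WT CMS and 2 of 5 in 5xFAD CMS. Choroid plexus and ependyma markers summed to 5324 CPM in WT CMS 2 and 2198 CPM in WT control 1, and to at most 914 CPM in the other 12 libraries. Erythroid markers reached 1782 CPM in WT CMS 2. Only 4 of the 12 B cell markers were measured, so that list was not tested, and its sum was 104 ± 9.08 CPM (n = 3) in WT control, 106 ± 6.68 (n = 3) in 5xFAD control, 108 ± 13.6 (n = 3) in WT CMS and 105 ± 1.65 (n = 5) in 5xFAD CMS.

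The comparison of unstressed 5xFAD with unstressed WT mice asked what the amyloid-bearing genotype changed in these cells. Genes of amyloid-associated microglia were far higher in 5xFAD. Cst7, which encodes cystatin F, an inhibitor of lysosomal cysteine proteases (ENSMUSG00000068129, protein-coding, chromosome 2 from 150412335 to 150420864), stood at 323 ± 158 scaled counts in WT control (n = 3) and 34758 ± 5336 in 5xFAD control (n = 3), a log2 fold change of 6.84 (SE 0.24; limma, Benjamini-Hochberg adjusted p = 5.41e-10). Apoe, the main lipid carrier of the brain (ENSMUSG00000002985, chromosome 7 from 19430034 to 19433113), rose from 45503 ± 4519 to 314840 ± 55746 (log2 fold change 2.78, SE 0.15; limma adjusted p = 3.53e-08). Lpl, lipoprotein lipase, rose from 884 ± 131 to 17205 ± 3120 (log2 4.28, SE 0.13; limma adjusted p = 2.79e-10). Trem2, a lipid-sensing receptor of microglia (ENSMUSG00000023992, chromosome 17 from 48653429 to 48661175), rose from 11805 ± 276 to 33900 ± 5816 (log2 1.51, SE 0.13; limma adjusted p = 2.29e-06). Tmem119, a surface marker of resting microglia, fell from 30519 ± 3417 to 14920 ± 3835 (log2 −1.06, SE 0.25; limma adjusted p = 0.00785).

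Of 16169 genes tested, 2371 rose and 1324 fell in 5xFAD control (limma, adjusted p 0.05), 583 and 623 of them by at least 2-fold. Unadjusted p was under 0.05 for 5989 genes, where 808 would be expected by chance. For 7407 genes (45.8%) the 2 groups did not overlap, against 10% by chance. The authors' deposited table (DESeq2) called 3897 genes, 2469 higher and 1428 lower, and 3541 of the 3695 genes called here were among them with the same sign. The share of calls that were higher, 64.2%, depended on scaling. It was 47.7% with upper-quartile scaling (1798 higher, 1974 lower) and 33.3% with library totals alone (1338 higher, 2685 lower), a scaling chosen after seeing the data that shifts the median of all genes by −0.17 log2, so changes are relative to that median. The lower count moved with single libraries and with other settings. It was 610 without 5xFAD control 1, 770 without WT control 1, 861 without WT control 3 and 749 without both choroid-rich libraries (WT control 1 and WT CMS 2, a setting chosen after seeing the data), and 2459 with voom with quality weights. With the X/Y balance as a covariate it was 2207, beside 2 of 3 Xist-high libraries in WT control and 1 of 3 in 5xFAD control.

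Of the 34 lists camera and fry each called 24 in unstressed mice, and camera with an estimated correlation called 0. The fry test asks whether a list changed by itself, not whether it changed more than other genes. All 30 genes of the list of disease-associated microglia rose (median log2 2.19), and all 30 passed when adjusted over the list alone. The camera set test passed (limma's camera, adjusted p = 1.01e-36) but not with an estimated correlation (adjusted p = 0.0818 with an estimated correlation). Beside Cst7, Apoe, Lpl and Trem2 they included Itgax, the integrin CD11c (log2 4.10), Clec7a, the beta-glucan receptor dectin-1 (3.20), and Gpnmb, a transmembrane glycoprotein of phagocytes, which went from 133 ± 68.0 to 14433 ± 4262 scaled counts (n = 3 each; log2 6.85). Baiap2l2, a membrane-bending protein, rose from 9.27 ± 5.98 to 1487 ± 228 (log2 7.34), and Trpm1, a cation channel outside the list, from 3.98 ± 3.59 to 546 ± 67.3 (log2 7.23). Other rises among the 10 largest were Lgi2 (6.54), Mamdc2 (6.04), the potassium channel Kcnk9 (6.0), the zinc transporter Tmem163 (5.80) and Pianp (5.24). In the list of homeostatic microglia genes, 6 of 20 fell, 2 rose and 12 did not pass, with 7 lower and 2 higher when adjusted over the list alone (median log2 −0.27; camera adjusted p = 0.0274, and adjusted p = 0.608 with an estimated correlation). The lens crystallin Crybb1, a microglial marker, fell by 1.46 on the log2 scale. The ADP receptor P2ry12 fell from 65331 ± 1973 to 48549 ± 5756 (log2 −0.43; limma adjusted p = 0.0173), a call that was lost without WT control 1 (log2 −0.40), WT control 3 (−0.38) or 5xFAD control 1 (−0.35), and without both choroid-rich libraries (−0.39).

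**Figure D1:**
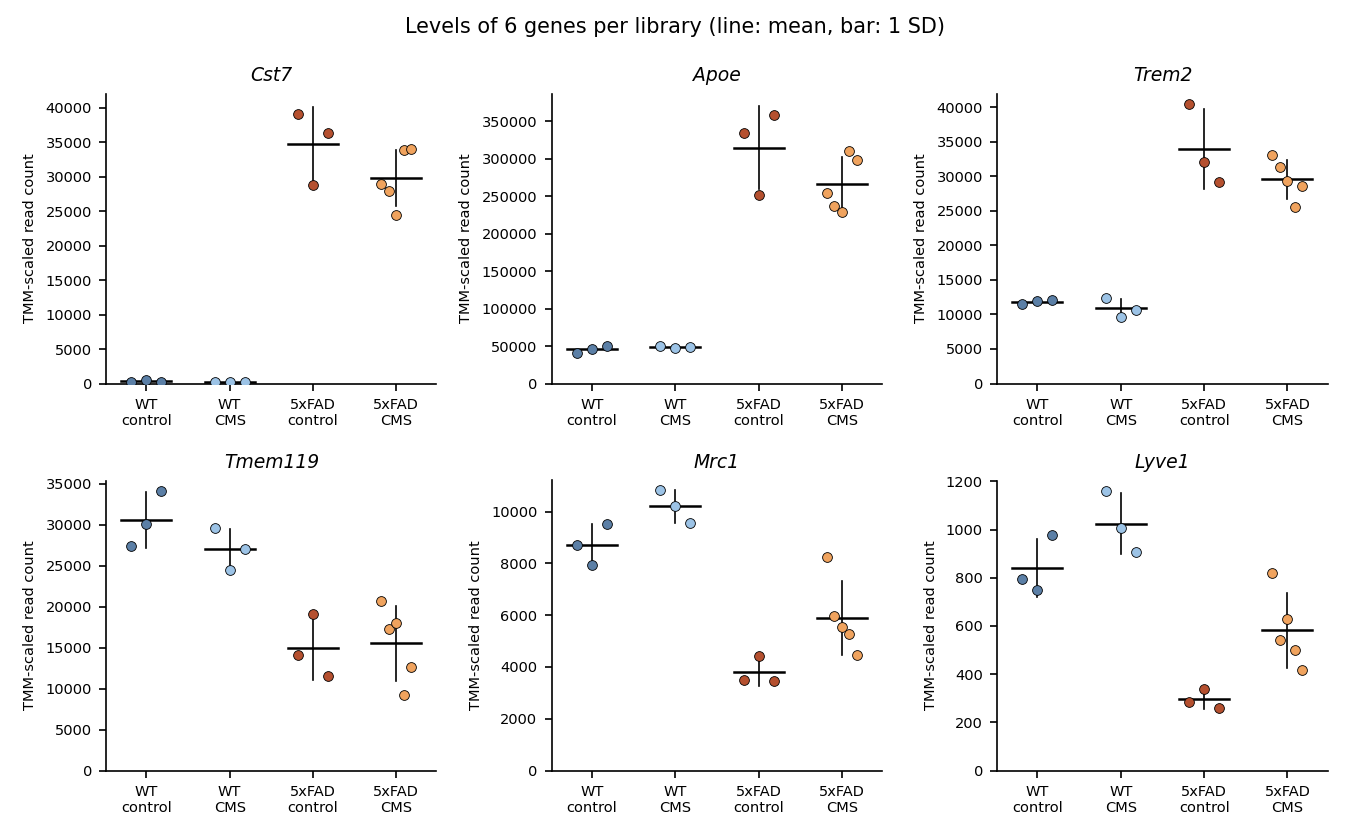
TMM-scaled read count per library (y axis, linear from 0) of Cst7, Apoe, Trem2, Tmem119, Mrc1 and Lyve1 in WT control, 5xFAD control, WT CMS (n = 3 each) and 5xFAD CMS (n = 5); points are libraries, lines group means and bars 1 SD. Cst7 lay at 323 and 194 on average in the WT groups and at 34758 and 29852 in the 5xFAD groups, whereas Mrc1 lay at 8710 and 10196 in the WT groups and at 3794 and 5894 in the 5xFAD groups.

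MHC class I and interferon response genes rose in 5xFAD control as well. In the MHC class I list 11 of 15 genes rose, and 14 when adjusted over the list alone (median log2 0.73; camera adjusted p = 5.79e-09, and adjusted p = 0.101 with an estimated correlation). B2m, the invariant light chain, rose from 35505 ± 2097 to 96889 ± 11362 (log2 1.44), and Psmb8, an immunoproteasome subunit, by 0.92 on the log2 scale. The heavy-chain genes of this list share sequence, so how reads were divided among them is uncertain. Of the type I interferon response genes 15 of 30 rose, the same number when adjusted over the list alone, led by Ifi27l2a (log2 2.00; camera adjusted p = 1.36e-05, and adjusted p = 0.261 with an estimated correlation). MHC class II genes went both ways, with 3 of 10 higher and 1 lower (3 and 3 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.460). In the complement list 7 of 17 rose and 2 fell (7 and 3 when adjusted over the list alone), with a median log2 of 0.01 and a mean of 0.19 (camera adjusted p = 0.143). C1qa, a chain of the classical pathway's recognition molecule, rose by 0.79 on the log2 scale, and Cfp, properdin, fell by 1.49. Of the 24 inflammatory cytokine and chemokine genes 5 rose and 3 fell, in all genes and when adjusted over the list alone (camera adjusted p = 0.491). The cytokine genes Il12b (log2 2.24) and Il1b (1.48) were among those that rose, and the monocyte chemoattractant gene Ccl7 (−1.15) among those that fell.

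Most lysosome, glycolysis and nuclear oxidative phosphorylation genes rose. In the lysosome and phagocytosis list 20 of 29 genes rose and 2 fell, 21 and 2 when adjusted over the list alone (median log2 0.88; camera adjusted p = 1.42e-10, and adjusted p = 0.158 with an estimated correlation). The protease gene Ctsb rose by 1.5 and the hexosaminidase gene Hexa by 1.48 on the log2 scale, and Atp6v0d2, a subunit of the vacuolar proton pump, by 5.13. The scavenger receptor Cd36, named after its values were seen, fell by 1.29. Lipid efflux and storage genes went both ways, 8 of 21 higher and 3 lower (9 and 3 when adjusted over the list alone; median log2 0.11, smaller than the −0.17 that library totals alone would take off, mean 0.75; camera adjusted p = 0.00220, and adjusted p = 0.0898 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 23 cases, 12 when adjusted over the list alone (median 0.53; camera adjusted p = 6.53e-06, and adjusted p = 0.209 with an estimated correlation). Of 16 glycolysis genes 12 rose and 1 fell, 13 and 1 when adjusted over the list alone (median 1.07; camera adjusted p = 1.75e-09, and adjusted p = 0.0898 with an estimated correlation), and Tpi1, triosephosphate isomerase, rose by 2.02. The nuclear genes of oxidative phosphorylation rose in 28 of 33 cases, 30 when adjusted over the list alone (median 0.76; camera adjusted p = 1.42e-16, and adjusted p = 0.115 with an estimated correlation), with Ndufa1 at 2.04 and Uqcrh at 1.26. Of the 8 mitochondrially encoded genes measured 2 rose, 5 when adjusted over the list alone (median 0.65; camera adjusted p = 0.00555, and adjusted p = 0.410 with an estimated correlation).

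Ribosomal protein genes rose in 44 of 45 cases, also when adjusted over the list alone (median log2 1.07; camera adjusted p = 8.18e-35, and adjusted p = 0.0898 with an estimated correlation). Rpl32 rose by 1.28 (SE 0.09) on the log2 scale, and the list took 0.685 ± 0.0530% of all counts in WT control and 1.27 ± 0.0595% in 5xFAD control (n = 3 each). These genes have many processed pseudogenes, so their counts are uncertain where reads were shared. Of the unfolded protein response genes 9 of 21 rose, 10 when adjusted over the list alone (median 0.23; camera adjusted p = 0.00113, and adjusted p = 0.25 with an estimated correlation). NRF2 antioxidant genes rose in 6 of 17 cases and fell in 1, with 8 and 1 when adjusted over the list alone (median 0.31; camera adjusted p = 0.0311, and adjusted p = 0.346 with an estimated correlation). Cell cycle genes rose in 2 of 25 cases, in all genes and when adjusted over the list alone (median 0.31; camera adjusted p = 0.0126, and adjusted p = 0.512 with an estimated correlation).

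Some genes that respond to acute stimulation fell in 5xFAD control. Of 25 immediate early genes 8 fell and 0 rose, 9 when adjusted over the list alone (median log2 −0.40; camera adjusted p = 0.000404, and adjusted p = 0.410 with an estimated correlation), and the list took 5.34 ± 0.908% of counts in WT control and 3.23 ± 0.205% in 5xFAD control (n = 3 each). The transcription factor genes Fos (log2 −0.61) and Atf3 (−0.87) were among them, and both calls were lost without WT control 3 (−0.45 and −0.67). Relative to the WT control mean its level was 0.16 and 0.23 log2 in the Xist-high libraries WT control 2 and 3 and −0.39 in the Y-high WT control 1. It was −0.46 and −0.38 in the Y-high 5xFAD control 1 and 2, and −0.50 in the Xist-high 5xFAD control 3. Of 15 heat shock and chaperone genes 6 fell, with 8 lower and 1 higher when adjusted over the list alone (median −0.59; camera adjusted p = 0.00210, and adjusted p = 0.410 with an estimated correlation), Hsph1 by 1.01 on the log2 scale. Glucocorticoid response genes did not pass as a list, with 4 of 24 higher and 6 lower (4 and 8 when adjusted over the list alone; camera adjusted p = 0.0794). The glucocorticoid receptor co-chaperone gene Fkbp5 had a log2 fold change of −0.27 (limma adjusted p = 0.471), and of −0.69 with the level of non-myeloid markers as a covariate, a setting chosen after seeing the data (limma adjusted p = 0.00547). TGF-beta signalling genes rose in 3 of 14 cases, 3 when adjusted over the list alone, with a median of −0.11 and a mean of 0.01 (camera adjusted p = 0.947). Of 13 alternative activation genes 7 fell and 1 rose, 9 and 1 when adjusted over the list alone (median −1.07; camera adjusted p = 0.00226, and adjusted p = 0.189 with an estimated correlation). The riser was Il1rn, the interleukin 1 receptor antagonist gene (1.56), named after its values were seen. Among 21 Alzheimer risk genes expressed in myeloid cells 4 rose and 3 fell, in all genes and when adjusted over the list alone (camera adjusted p = 0.491).

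Markers of border-associated macrophages, the macrophages of meninges and perivascular spaces, fell in 13 of 13 cases in 5xFAD control, also when adjusted over the list alone (median log2 −1.20; camera adjusted p = 2.56e-09, and adjusted p = 0.143 with an estimated correlation). The mannose receptor gene Mrc1 fell from 8710 ± 800 to 3794 ± 537 scaled counts (log2 −1.20; limma adjusted p = 0.000209), the hyaluronan receptor gene Lyve1 from 841 ± 122 to 295 ± 39.2 (log2 −1.51; limma adjusted p = 0.000103), and the clotting factor gene F13a1 by 1.38 on the log2 scale. Summed, the markers were at 2162 ± 202 CPM in WT control and 797 ± 143 CPM in 5xFAD control. Ms4a4a, a gene of an Alzheimer risk locus with close paralogs beside it, fell by 1.55. Of 15 monocyte markers 9 fell and 1 rose, 10 and 1 when adjusted over the list alone (median −1.49; camera adjusted p = 0.000493, and adjusted p = 0.231 with an estimated correlation). The chemokine receptor gene Ccr2 fell by 1.49, and the riser was the lysozyme gene Lyz2 (log2 1.27), which macrophages express as well. Neutrophil markers fell in 5 of 15 cases and in 13 when adjusted over the list alone (median −1.61; camera adjusted p = 0.000292, and adjusted p = 0.411 with an estimated correlation). Dendritic cell markers fell in 5 of 10 cases, 6 when adjusted over the list alone (median −1.05; camera adjusted p = 0.0126, and adjusted p = 0.143 with an estimated correlation). T and NK cell markers went both ways, 2 of 10 higher and 3 lower (2 and 4 when adjusted over the list alone; camera adjusted p = 0.103), and 0 of 8 erythroid markers passed, also when adjusted over the list alone (median −0.96; camera adjusted p = 0.112).

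Markers of cells that are not myeloid were lower on average too, though most did not pass singly. This sets the composition of the isolates beside the gene changes above. Averaged over 6 such lists, the level was −0.76 ± 0.28 log2 in 5xFAD control against 0 ± 0.44 in WT control (n = 3 each). Neuron markers fell in 3 of 13 cases, 6 when adjusted over the list alone (camera adjusted p = 0.00833, and adjusted p = 0.388 with an estimated correlation), and endothelial and mural markers in 1 of 15, 0 when adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.608 with an estimated correlation). Oligodendrocyte markers fell in 4 of 15 cases and rose in 1, with 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00572, and adjusted p = 0.512 with an estimated correlation). The riser, named after its values were seen, was the proteoglycan gene Cspg4 (log2 1.54), which oligodendrocyte precursors and pericytes express. Of 13 astrocyte markers 2 fell and 1 rose, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0790). The riser was Gfap, the intermediate filament gene of reactive astrocytes, at 164 ± 110 scaled counts in WT control and 1101 ± 79.1 in 5xFAD control (log2 2.94; limma adjusted p = 0.000130). In the choroid plexus and ependyma list 0 of 10 passed, also when adjusted over the list alone (camera adjusted p = 0.204).

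The 10 largest falls among genes with a mean of at least 50 and no overlap between the groups were between −2.14 and −1.82 on the log2 scale. They were Iqch, the endothelial adhesion gene Sele, the subcommissural organ gene Sspo, the neutrophil citrullinating enzyme gene Padi4, the sugar transporter gene Slc5a10, the inhibitory lectin gene Siglecg, the adrenergic receptor gene Adra2a, the ciliary dynein gene Dnah3, the haptoglobin gene Hp and the protease gene Napsa. Iqch, at −2.14, also differed between Xist-high and Y-high libraries (log2 1.14; limma adjusted p = 0.00535). Calls were lost for Sele without WT control 1 (−1.49) or 5xFAD control 2 (−1.62), and for Adra2a without 5xFAD control 1 (−1.42). That of Dnah3 was lost without WT control 1 (−1.43), 5xFAD control 1 (−1.59) or 5xFAD control 2 (−1.80). That of Hp was lost without WT control 1 (−1.64), WT control 3 (−1.43) or 5xFAD control 1 (−1.69), and that of Napsa without 5xFAD control 1 (−1.5). Without both choroid-rich libraries those of Sele (−1.48), Dnah3 (−1.42), Hp (−1.63) and Napsa (−1.78) were lost, and that of Hp also with voom (−1.5), with no filter beyond 1 count (−1.84) and with the non-myeloid covariate (−1.80). The neutrophil gelatinase gene Mmp9 fell by 1.81, a call lost without WT control 1 (−1.67), WT control 3 (−1.33), 5xFAD control 1 (−1.63) or 5xFAD control 2 (−1.69), without both choroid-rich libraries (−1.67), with no filter beyond 1 count (−1.83) and with the non-myeloid covariate (−1.90).

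The mouse genes App and Thy1 did not pass for genotype. App (ENSMUSG00000022892, chromosome 16 from 84746573 to 84970654) was at 12107 ± 1971 scaled counts in WT control and 12179 ± 430 in 5xFAD control (log2 0.02; limma adjusted p = 0.939), and its sign turned with upper-quartile scaling (−0.07) and with library totals alone (−0.15). Thy1, at 12.8 ± 3.68 and 16.0 ± 3.79 scaled counts, had a log2 fold change of 0.32 (limma adjusted p = 0.536). These are counts of mouse genes, and transcripts of the human transgenes were not analysed here.

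The same genotype comparison was made between stressed mice, to ask whether the 5xFAD difference was also present under chronic mild stress. Cst7 rose from 194 ± 15.1 scaled counts in WT CMS (n = 3) to 29852 ± 4085 in 5xFAD CMS (n = 5), a log2 fold change of 7.25 (SE 0.21; limma adjusted p = 6.44e-11). Apoe rose from 48470 ± 1033 to 265650 ± 36668 (log2 2.44; limma adjusted p = 2.74e-08), Lpl by 4.20, Itgax by 4.07, Clec7a by 3.19 and Trem2 by 1.45. The largest rises were Trpm1 (7.61), Baiap2l2 (7.38), Cst7, Gpnmb (6.84), Atp6v0d2 (5.96), Mamdc2 (5.59), Pianp (5.49), Kcnk9 (5.33), Lgi2 (5.23) and the Wnt antagonist gene Dkk2 (4.94). Tmem119 fell by 0.85 (limma adjusted p = 0.0154) and P2ry12 by 0.36 (limma adjusted p = 0.0261), and both calls were lost without WT CMS 1 (−0.79 and −0.25) and with the replicate number as a block (−0.54 and −0.34). That of Tmem119 was also lost with the non-myeloid covariate (−0.87), and that of P2ry12 in a fit of only the libraries compared (−0.36). The mouse genes App (−0.17), Thy1 (0.54) and Fkbp5 (0.08) did not pass (limma adjusted p = 0.406, 0.212 and 0.814), and Fkbp5 turned negative with library totals alone (−0.10).

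In stressed mice 2449 genes rose and 1446 fell in 5xFAD (limma, adjusted p 0.05), 491 and 666 of them by at least 2-fold. Unadjusted p was under 0.05 for 6580 genes, and 4035 (25.0%) did not overlap between the groups, against 3.57% by chance. The authors' deposited table (DESeq2) called 4399 genes, 2294 higher and 2105 lower, which included 3670 of the 3895 genes called here with the same sign. The share of higher calls was 62.9%, and 44.5% with upper-quartile scaling (1818 higher, 2264 lower) or 28.2% with library totals alone (1300 higher, 3308 lower), where the median of all genes shifts by −0.18 log2. The higher count was 1599 without WT CMS 2. The lower count was 564 without WT CMS 2, 922 without WT CMS 1, 893 without 5xFAD CMS 4, 875 without 5xFAD CMS 5, 472 without both choroid-rich libraries, 759 in a fit of only the libraries compared, 626 with the non-myeloid covariate and 479 with the replicate number as a block. Of the genes called in either comparison 2019 rose in both and 794 fell in both, where independent lists would share 359 and 118, and 0 were called in opposite directions. Across genes the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.887 and a covariance of 0.40. The comparisons share no library, and genes are not independent replicates.

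Under stress the camera test passed for 26 of 34 lists, and for 0 with an estimated correlation. The fry test passed for 20. All 30 disease-associated microglia genes rose, also when adjusted over the list alone (median log2 2.08; adjusted p = 0.0746 with an estimated correlation), as did 44 of 45 ribosomal protein genes, 45 when adjusted over the list alone (median 0.95; adjusted p = 0.121 with an estimated correlation). Oxidative phosphorylation genes rose in 26 of 33 cases, glycolysis genes in 12 of 16 with 1 lower, lysosome genes in 20 of 29 with 1 lower and MHC class I genes in 11 of 15, and 30, 13 and 1, 21 and 1, and 13 when adjusted over the list alone (adjusted p = 0.152, 0.121, 0.152 and 0.152 with an estimated correlation). Interferon response genes rose in 11 of 30 cases and fell in 1, 12 and 1 when adjusted over the list alone (adjusted p = 0.338 with an estimated correlation). Cell cycle genes rose in 10 of 25 cases and in 13 when adjusted over the list alone (median 0.55; camera adjusted p = 0.000143, and adjusted p = 0.338 with an estimated correlation), with the mitotic kinase gene Cdk1 at 1.16. Homeostatic genes fell in 6 of 20 cases and rose in 3, in all genes and when adjusted over the list alone (camera adjusted p = 0.156). Of 25 immediate early genes 1 fell, also when adjusted over the list alone (median −0.30; camera adjusted p = 0.00767, and adjusted p = 0.488 with an estimated correlation).

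Border-associated macrophage markers fell in 10 of 13 cases in stressed 5xFAD mice, 12 when adjusted over the list alone (median −0.82; camera adjusted p = 2.11e-06, and adjusted p = 0.252 with an estimated correlation), with Mrc1 at −0.82, Lyve1 at −0.85 and F13a1 at −0.76. Their sum was 2287 ± 215 CPM in WT CMS and 1132 ± 263 CPM in 5xFAD CMS. Monocyte markers fell in 9 of 15 cases and rose in 1, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.00326, and adjusted p = 0.338 with an estimated correlation), and 0 of 15 neutrophil markers passed (camera adjusted p = 0.00141, and adjusted p = 0.485 with an estimated correlation). Oligodendrocyte markers fell in 11 of 15 cases with 1 higher, and astrocyte markers in 6 of 13 with 1 higher, 13 and 1, and 10 and 1 when adjusted over the list alone (adjusted p = 0.451 and 0.485 with an estimated correlation). The largest falls were between −1.95 and −1.53. They included the neutral amino acid transporter gene Slc7a10, Napsa, the glutamate receptor gene Grin2c, Sspo, the planar polarity gene Celsr1, Aifm3, the oligodendrocyte transcription factor gene Sox10, Gdf10 and the adhesion gene Cadm2. Without WT CMS 2, which was rich in choroid plexus markers, the calls of Slc7a10 (−1.46), Grin2c (−1.46), Sspo (−1.45), Celsr1 (−1.27), Aifm3 (−1.17), Sox10 (−1.17) and Cadm2 (−1.07) were lost, and with the non-myeloid covariate they were lost as well (−0.73, −0.72, −1.29, −0.62, −0.59, −0.59 and −0.40), as were those of Napsa (−1.57) and Gdf10 (−0.78). Without both choroid-rich libraries the same 7 calls (−1.42, −1.43, −1.42, −1.23, −1.14, −1.14 and −1.03) and that of Napsa (−1.63) were lost. With the replicate number as a block the 7 (−1.47, −1.16, −1.12, −1.13, −1.34, −1.19 and −1.17) and Gdf10 (−1.30) were lost. Grin2c was also lost without WT CMS 1 (−1.64) and with only the libraries compared (−1.68), and Sspo with voom (−1.08). Cadm2 was also lost without 5xFAD CMS 1 (−1.44), 5xFAD CMS 4 (−1.54) or 5xFAD CMS 5 (−1.25), with voom (−1.19), with no filter beyond 1 count (−1.53) and with only the libraries compared (−1.53).

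**Figure D2:**
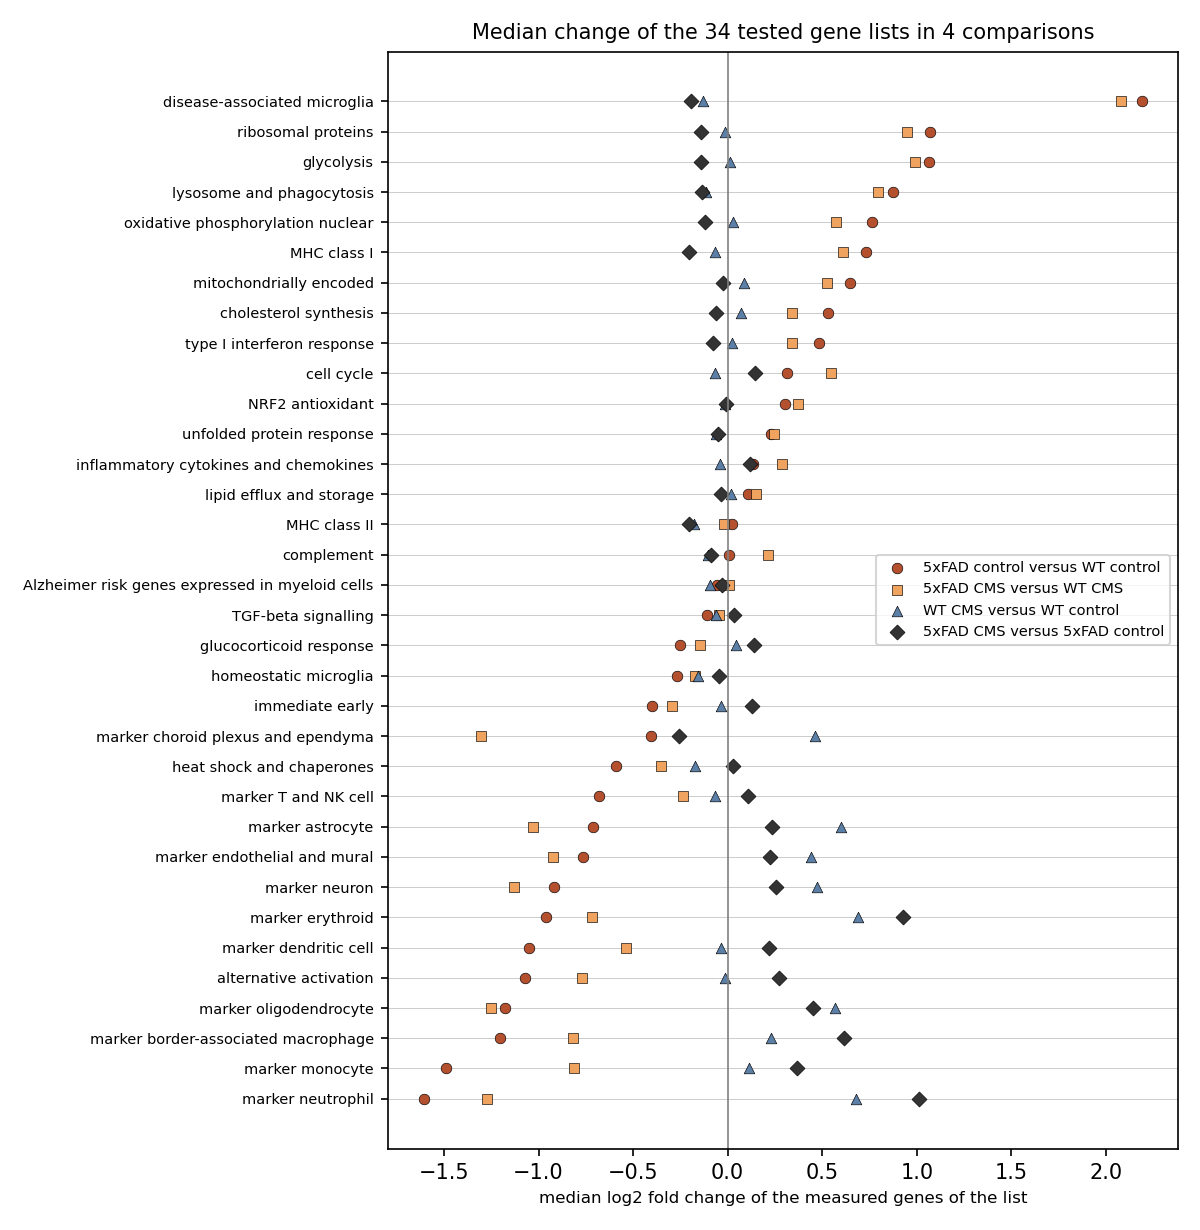
Median log2 fold change (x axis) of the measured members of each of 34 gene lists (y axis) in 4 comparisons, marked by symbol. In the unstressed and stressed genotype comparisons disease-associated microglia genes lay at 2.19 and 2.08 and border-associated macrophage markers at −1.20 and −0.82, and under stress in 5xFAD these lists lay at −0.19 and 0.61.

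In WT mice chronic mild stress was compared with no stress to ask what stress alone changed. No gene passed. The 5 genes with the smallest p were Cdkn2a, the p16 and p19 cell cycle inhibitor gene (5.93 ± 0.897 scaled counts in WT control and 1.97 ± 0.264 in WT CMS, n = 3 each; log2 −1.22), Pcdhgb7 (0.66), Plekhf1 (1.09), Gm8075 (−1.70) and Gm50399 (−1.65), each with a limma adjusted p of 0.9997. Gm8075 is a long non-coding RNA gene with 4.23 ± 2.22 and 0.848 ± 1.47 scaled counts, and its counts are uncertain where reads were shared with near-identical copies. Cst7 had a log2 fold change of −0.63, Trem2 of −0.13, Apoe of 0.10, Itgax of −0.17, Clec7a of −0.16, Tmem119 of −0.17, P2ry12 of −0.12, App of 0.23 and Thy1 of 0.79, and none passed. Cst7 was at 506 scaled counts in WT control 2 and at 230 and 233 in the other WT control libraries, and without WT control 2 its log2 fold change was −0.25. Fkbp5, a target of glucocorticoid signalling, had a log2 fold change of 0.02 (SE 0.26). limma called 0 of 16169 genes, with 139 at an unadjusted p under 0.05 where 808 would be expected by chance, voom with quality weights called 0, and the authors' deposited table (DESeq2) held 0. The 2 groups did not overlap for 673 genes (4.16%, against 10% by chance). In simulated libraries of this comparison's size 77.7% of genes changed by 2-fold and 43.7% of those changed by 1.5-fold were called. Only genes with a mean of at least 50 were changed there, and the libraries held no structure by sex or composition.

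As lists, 15 of 34 passed camera in WT CMS and 0 with an estimated correlation (smallest adjusted p = 0.670 with an estimated correlation) or with fry. In none of them did a gene pass, also when adjusted over the list alone. The 7 lists called upward were markers of neutrophils (median log2 0.68), erythroid cells (0.69), neurons (0.47), astrocytes (0.60), oligodendrocytes (0.57), endothelial and mural cells (0.44) and border-associated macrophages (0.23). The 8 called downward were homeostatic microglia (−0.16, 0 of 20 members above 0), disease-associated microglia (−0.13), lysosome (−0.12), MHC class II (−0.18), MHC class I (−0.07), heat shock (−0.17), unfolded protein response (−0.06) and Alzheimer risk genes (−0.09). Glucocorticoid response genes had a median of 0.04 (camera adjusted p = 0.570). The choroid-rich library WT CMS 2 also held the most oligodendrocyte marker counts (1803 CPM), and the number of lists called was 8 without it and 7 with the level of non-myeloid markers as a covariate, chosen after seeing the data. The level of the 6 non-myeloid lists was 0.54 ± 0.76 log2 in WT CMS against 0 ± 0.44 in WT control (n = 3 each).

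In 5xFAD mice the comparison of stressed with unstressed animals asked what chronic stress changed once the mice carry amyloid. No gene passed here, and the 5 genes with the smallest p each had a higher mean under stress. Of these, F13a1 and Lyve1 are in the border-associated macrophage list, Ms4a4a is in the Alzheimer risk list, and Vnn3 and Ccr1 are in neither. Ms4a4a (ENSMUSG00000101389, chromosome 19 from 11352887 to 11370154) was at 115 ± 6.81 scaled counts in 5xFAD control (n = 3) and 223 ± 33.8 in 5xFAD CMS (n = 5), a log2 fold change of 0.94 (SE 0.16; limma adjusted p = 0.471). F13a1 (ENSMUSG00000039109, chromosome 13 from 37051152 to 37234220) was at 1453 ± 150 and 2507 ± 464 (log2 0.77, SE 0.14; limma adjusted p = 0.471), and Lyve1 (ENSMUSG00000030787, chromosome 7 from 110449814 to 110462446) at 295 ± 39.2 and 581 ± 154 (log2 0.95, SE 0.18; limma adjusted p = 0.633). Vnn3, a pantetheinase gene, was at 13.2 ± 2.35 and 29.1 ± 4.52 (log2 1.08) and the chemokine receptor gene Ccr1 at 239 ± 36.2 and 424 ± 104 (log2 0.81), both with a limma adjusted p of 0.633. The haemoglobin scavenger receptor gene Cd163 (0.77) and Mrc1 (0.61) did not pass either. The authors' deposited table (DESeq2) called 4 genes, all higher under stress. They were Ms4a4a (log2 0.92, adjusted p = 0.0168), F13a1 (0.75, adjusted p = 0.0168), Lyve1 (0.94, adjusted p = 0.0168) and the mycobacterial lectin receptor gene Clec4e (1.19, adjusted p = 0.0494), and limma put Clec4e, named because of that call, at 1.16 with an adjusted p of 0.633.

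Apoe (log2 −0.24), Cst7 (−0.22), Itgax (−0.19), Trem2 (−0.19), Clec7a (−0.18), Tmem119 (0.03) and P2ry12 (−0.05), which passed for genotype, did not pass for stress, each with a limma adjusted p of 0.9999. App (0.04), Thy1 (1.01) and Fkbp5 (0.38) had the same adjusted p. Thy1 was at 11.7 to 18.7 scaled counts in 5xFAD control (n = 3) and 20.9 to 45.3 in 5xFAD CMS (n = 5), with no overlap. The sign of Tmem119 turned with median-of-ratios scaling (−5e-04). limma called 0 of 16169 genes, with 478 at an unadjusted p under 0.05 (358 higher, 120 lower) where 808 would be expected by chance, and voom called 0. The 2 groups did not overlap for 397 genes (2.46%, against 3.57% by chance). Without 5xFAD CMS 5 the bone morphogenetic protein gene Bmp2 (0.97) and Ccl7 (0.91) passed, both named after their values were seen, against 0.74 and 0.69 in all libraries, and with the non-myeloid covariate Ms4a4a passed (1.05). In simulated libraries of this comparison's size 78.6% of genes changed by 2-fold and 55.2% of those changed by 1.5-fold were called. The changed genes all had a mean of at least 50, and these libraries held no structure by sex or composition.

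At the level of lists, 20 of 34 passed camera in stressed 5xFAD mice, and 0 with an estimated correlation or with fry. Border-associated macrophage markers were higher in 13 of 13 cases, of which 0 passed over all genes and 9 when adjusted over the list alone (median log2 0.61; camera adjusted p = 1.65e-18, and adjusted p = 0.151 with an estimated correlation). The number that passed over the list alone was 5 without 5xFAD control 1 and 13 with voom. Monocyte markers (0.37, 13 of 15 above 0), neutrophil markers (1.01, 15 of 15), erythroid markers (0.93), neuron markers (0.26), oligodendrocyte markers (0.45), alternative activation genes (0.27), inflammatory genes (0.12) and immediate early genes (0.13) were also called upward, with adjusted p = 0.259, 0.316, 0.316, 0.316, 0.480, 0.259, 0.480 and 0.679 with an estimated correlation. When adjusted over the list alone, 3 alternative activation genes, 2 neuron markers and 1 Alzheimer risk gene passed, all higher. Stfa2l1, a neutrophil stefin gene with near-identical copies, had the smallest p of its list (log2 1.25). The lists called downward were led by ribosomal proteins (−0.14, 1 of 45 above 0), MHC class I (−0.20, 1 of 15), disease-associated microglia (−0.19, 3 of 30), oxidative phosphorylation (−0.12, 0 of 33) and MHC class II (−0.20, 0 of 10), and adjusted p = 0.259, 0.151, 0.259, 0.259 and 0.259 with an estimated correlation. Lysosome (−0.13), glycolysis (−0.14), cholesterol synthesis (−0.06), interferon response (−0.08), unfolded protein response (−0.05, mean −0.01) and lipid efflux genes (−0.04) followed, with adjusted p = 0.316, 0.259, 0.427, 0.480, 0.427 and 0.259 with an estimated correlation. Glucocorticoid response genes did not pass, with 0 of 24 also when adjusted over the list alone (median 0.14, 15 of 24 above 0; camera adjusted p = 0.143). In the MHC class I list 2 genes passed when adjusted over the list alone, both lower, and Psmb8 (−0.26) and H2-T22 (−0.33), a gene with near-identical copies, had its smallest p.

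Exact permutation tests of the mean level of each list over the 56 splits of the 8 5xFAD libraries (two-sided) gave p = 0.0179, the smallest that 56 splits can give, for MHC class I and oxidative phosphorylation, 0.0357 for monocyte markers and 0.0536 for border-associated macrophage markers and for glucocorticoid response genes. None of the 34 lists passed adjustment in these exact tests (adjusted p = 0.304 for the first 2 and 0.364 for the other 3). The disease-associated microglia level was 2.91 ± 0.23 log2 above WT control in 5xFAD control (n = 3) and 2.72 ± 0.19 in 5xFAD CMS (n = 5), the border-associated macrophage level −1.17 ± 0.13 and −0.58 ± 0.31, the glucocorticoid response level −0.30 ± 0.05 and −0.15 ± 0.09, and the ribosomal protein level 1.05 ± 0.12 and 0.91 ± 0.09. Non-myeloid markers moved beside them, from −0.76 ± 0.28 to −0.40 ± 0.68. Among the 3695 genes called for genotype in unstressed mice, 91.2% had a stress difference of the opposite sign in 5xFAD mice, with medians of −0.10 for those that had risen and 0.25 for those that had fallen. Both comparisons use the same 3 5xFAD control libraries, which alone gives opposite signs, and in 60 simulations with genotype effects and no stress effect the share was 16.6% to 87.7% (median 65.0%). Chance is not excluded, since 11 of the 56 splits of the 8 5xFAD libraries gave a covariance of the 2 effects as low as the real one.

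**Figure D3:**
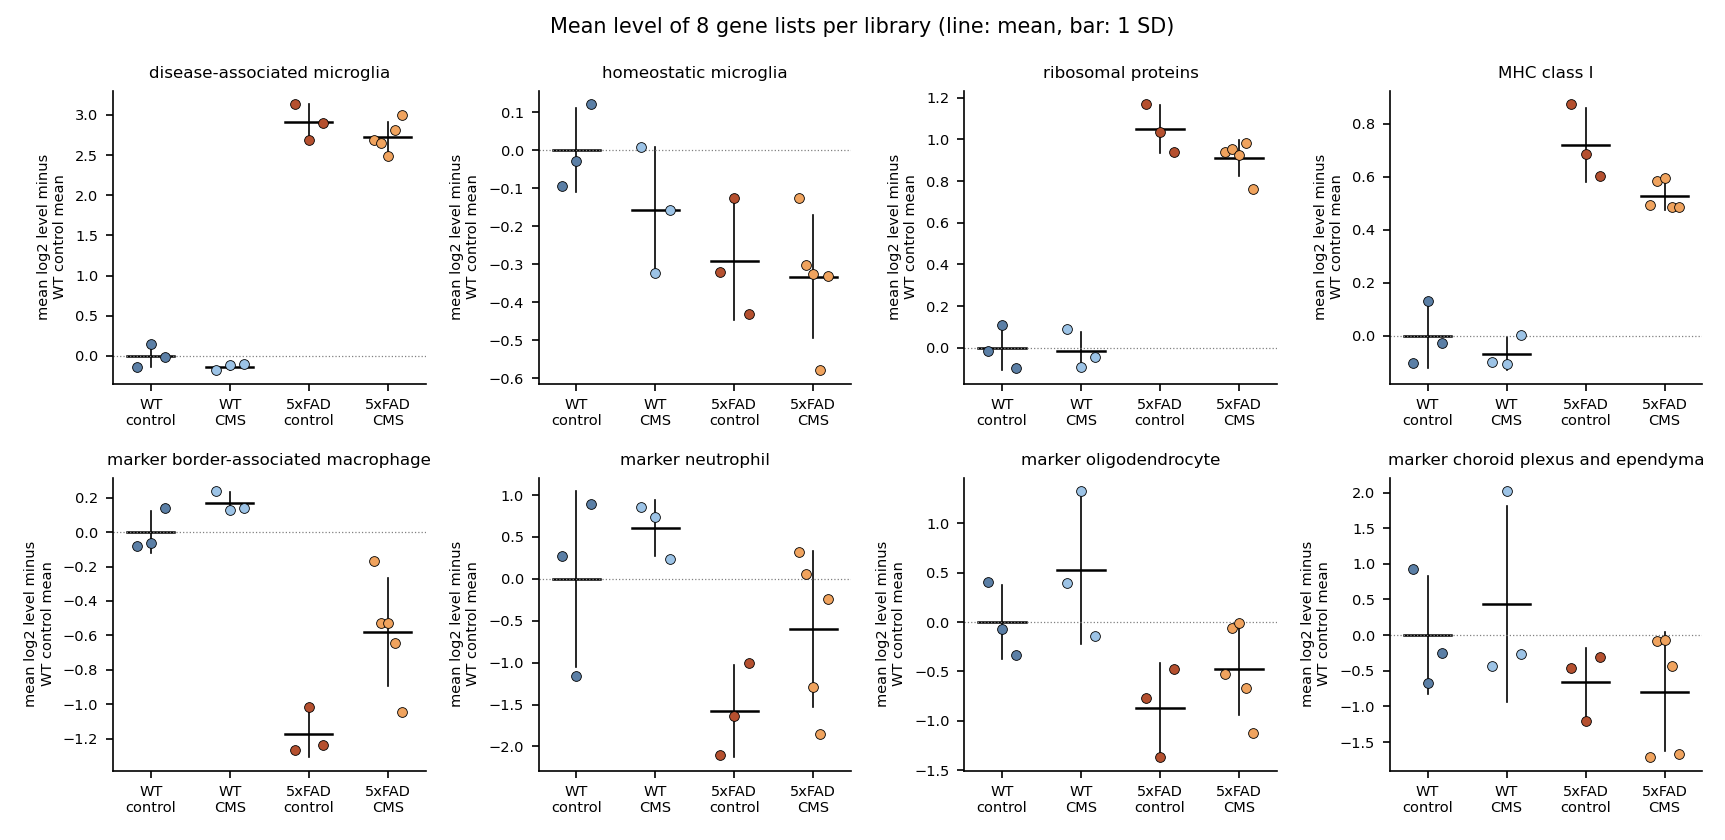
Mean log2 level of 8 gene lists per library, minus the WT control mean (y axis), in the 4 groups; points are libraries, lines group means and bars 1 SD (n = 3, 3, 3 and 5). Border-associated macrophage markers lay at −1.17 in 5xFAD control and −0.58 in 5xFAD CMS, whereas disease-associated microglia genes lay at 2.91 and 2.72.

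The interaction of genotype and stress asked whether stress acted differently in 5xFAD and WT mice. No gene passed. The 5 with the smallest p were Ly6m (log2 1.95), a member of a family with near-identical copies, Gm47079 (1.56), C330018A13Rik (1.23), Gm34455 (−1.27) and 4930430E12Rik (1.05), each with a limma adjusted p of 1. Apoe had an interaction of −0.34, Cst7 of 0.41, Trem2 of −0.06, Itgax of −0.03, Clec7a of −0.01, Tmem119 of 0.21, P2ry12 of 0.07, App of −0.19, Thy1 of 0.22 and Fkbp5 of 0.36, none of which passed. That of Cst7 was 0.04 without WT control 2 and 0.65 with voom. limma called 0 of 16169 genes, with 146 at an unadjusted p under 0.05 where 808 would be expected by chance, and voom called 0. The median standard error of the interaction was 0.242 log2, against 0.161 for stress in 5xFAD mice.

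Of the 34 lists 17 passed camera for the interaction, 9 upward and 8 downward, and 0 with an estimated correlation (smallest adjusted p = 0.461 with an estimated correlation) or with fry. The number called was 8 without WT control 3, 10 without 5xFAD control 1 and 10 without WT CMS 2. Border-associated macrophage markers had a median interaction of 0.38 with 13 of 13 above 0, homeostatic microglia genes 0.10 with 19 of 20 above 0, ribosomal proteins −0.12 and oxidative phosphorylation genes −0.16, and 0 members of these lists passed when adjusted over the list alone. A permutation test of the list means over 1120 regroupings passed for 0 of 34 lists. The smallest p in this permutation test was 0.126 for dendritic cell markers (adjusted p = 0.879), and border-associated macrophage markers had p = 0.165.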

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

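The tests of macrophage markers, the sex covariate and the splits for opposite signs, and the tests of a male WT admixture and of index misassignment, were chosen only after the result was seen. In 5xFAD CMS, the only group with more than 3 libraries, 125 values were tested for a library far from the other 4, and 8 passed the critical gap of 0.71, where chance gives about 1 in 20.

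5xFAD CMS 5 lay below the other 4 in oxidative phosphorylation level (0.465 against 0.6056 to 0.6306 log2 over WT control), ribosomal protein level (0.7631 against 0.9248 to 0.9816), share of counts in ribosomal protein genes (1.03% against 1.2% to 1.231%) and lipid efflux level (0.6639 against 0.7198 to 0.7306). In the same library Il1b was at 28780 scaled counts (others 12410 to 16820) and Ccl7 at 775.3 (others 1596 to 1753). Uqcrh was at 2421 in 5xFAD CMS 4 (others 1796 to 1955), and Ccr1 at 609.9 in 5xFAD CMS 1 (others 359.2 to 388.4).

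Border-associated macrophage markers were higher in stressed than in unstressed 5xFAD mice, with a median log2 fold change of 0.61 over 13 markers. As the whole cause, different numbers of male and female mice are argued against, since the median was 0.632 with the X/Y balance as a covariate (stress coefficient of the marker level 0.60, SE 0.15). With the non-myeloid level as a covariate the median was 0.550 (stress coefficient 0.57, SE 0.17), and the slope on that level was 0.05 (SE 0.12). This fit goes against more non-myeloid RNA as the whole cause, but the direct difference of the levels does not decide it. The macrophage level minus the non-myeloid level was −0.19 ± 0.62 (n = 5) with stress and −0.41 ± 0.38 (n = 3) without (exact permutation p = 0.607). A lower share of microglia stays open, since the macrophage level minus the mean of the other 10 marker lists was −0.16 ± 0.37 (n = 5) with stress and −0.35 ± 0.30 (n = 3) without (exact permutation p = 0.446). That mean itself was −0.42 ± 0.43 with stress and −0.82 ± 0.21 without (exact permutation p = 0.196). Markers of neutrophils (0.98), monocytes (0.46), erythroid (1.01) and dendritic cells (0.19) were higher on average too. So were those of neurons (0.48), oligodendrocytes (0.39), endothelial and mural cells (0.26), T and NK cells (0.22) and astrocytes (0.19). Those of choroid plexus and ependyma were lower on average (−0.134). Chance is not excluded (exact permutation p = 0.0536 over 56 splits). A response of these macrophages to stress, or more of them in the isolates, may account for the pattern and remains a hypothesis.

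Stress effects in 5xFAD mice had the opposite sign to genotype effects in 91.2% of the 3695 genes called for genotype. The shared 5xFAD control libraries lower the covariance by construction (mean −0.0565 in 200 simulations, 21 of them at or below the observed −0.113). With no shared library the covariance was below 0 in each of 3 splits, −0.0674 at the highest. These splits reuse the same libraries and have no simulated range beside them. They cannot part sharing together with chance from another cause. With the non-myeloid level and the X/Y balance as covariates the share of opposite signs was 91.5% and 90.0%. Both lay above the highest share in the 60 simulations with no stress effect (87.7%). Those simulations held no covariate, and the shared libraries stay in both fits. The shares thus do not decide on non-myeloid RNA or different numbers of male and female mice. Chance is not excluded, as 11 of the 56 splits of the 8 5xFAD libraries gave a covariance as low (lowest other −0.169). A partial return of the genotype difference under stress may account for the pattern and stays a hypothesis.

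The Xist-high library WT control 2 held 106 counts of Y-linked genes, 1.29% of the mean of Y-high libraries, where the other Xist-high libraries held at most 5. Index misassignment over the whole run is argued against, since those libraries reached at most 0.0761% of that mean. A small admixture of a male library stays open, and a 5xFAD and a WT source cannot be told apart: 13 genes high in 5xFAD had a median excess of 1.03% of their 5xFAD level over WT control 3, from −3.57% to 2.86% (10 of 13 above 0). The same genes had a median excess of 0.445% in WT control 1. That library is Y-high, so Y-linked counts could not show an admixture in it, and it is no reference known to be free of one. No biological explanation was tested.

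The other splits of the same libraries were counted for each comparison. For genotype without stress the real split gave 3695 genes (highest other 0) and 24 lists (highest other 23), each in 1 of 10 splits, and for stress in WT 15 lists (highest other 21; 4 of 10), and 10 splits are too few for a share under 0.05. For genotype under stress chance is excluded at 0.05 for genes (3895, highest other 2424; 1 of 56 splits) and for the number of lists (26, highest other 24; 1 of 56). Over these 56 splits the median was 13 lists, and 0 lists passed for the real split with an estimated correlation. The number thus does not vouch for single lists. For the lists of the interaction chance is not excluded (17, highest other 20; 17 of 100). For stress in 5xFAD the share for lists is under 0.05 (20, highest other 20; 2 of 56), but another split equals the real one, and 0 lists passed with an estimated correlation, with fry or in adjusted exact tests, so this count alone does not settle chance. With 0 genes called, every split gives as many, so the counts for stress in WT (highest other 9; 10 of 10), stress in 5xFAD (highest other 854; 56 of 56) and the interaction (highest other 0; 100 of 100) decide nothing on chance. The splits with 854 and 9 genes part Xist-high from Y-high libraries exactly, a structure of the samples, and 827 and 8 of those genes are not on X or Y.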

How the results depend on the processing

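Library totals alone, the non-myeloid covariate and leaving out both choroid-rich libraries were chosen only after the result was seen. So was the X/Y balance as a covariate for the lists and for the opposition. The other settings were fixed beforehand. For counts of genes and lists and the opposition, 350 values stayed within 1.5 times or 1 SD, 30 moved beyond, 8 counts of lists fell to 0 and 2 counts of genes went from 0 to 1 and 2. For named genes 3893 values kept their direction and side of the threshold, 77 were no longer past it, 4 newly passed and 55 turned sign. The cause was not tested unless named. Depth was not varied. In simulated libraries of each comparison's size, of genes with a mean of at least 50 changed 1.5-fold, 47.4% were recovered for genotype without stress, 43.7% for stress in WT, 55.2% for stress in 5xFAD and 45.9% for genotype under stress, with 6.32%, 6.44%, 7.14% and 5.92% false calls. Structure by sex or composition was not simulated.

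The values that moved or turned follow by setting. Library totals alone: genotype without stress 1338 higher and 2685 lower, genotype under stress 1300 and 3308, App −0.15 for genotype without stress, and Fkbp5 −0.0959 for genotype under stress. Upper-quartile scaling: genotype under stress 2264 lower, and App −0.0669 for genotype without stress. Median-of-ratios scaling: Tmem119 −5e-04 for stress in 5xFAD. A 2-fold threshold, which by construction lets fewer genes pass: 583 higher and 623 lower for genotype without stress, 491 and 666 under stress. A minimum mean of 50: App −0.0158 for genotype without stress. No filter beyond 1 count: Clec7a 0.0044 for the interaction. voom with quality weights: 2459 lower for genotype without stress, Fkbp5 −0.17 for genotype under stress, and for the interaction Itgax 0.0818 and P2ry12 −0.0367. X/Y balance as covariate: 2207 lower and App −0.0364 for genotype without stress. Only the libraries compared: 759 lower for genotype under stress.

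Without both choroid-rich libraries, which leaves fewer samples: 749 lower for genotype without stress and 472 under stress, App 0.0519 and Fkbp5 −0.0942 for genotype under stress, Fkbp5 −0.12 for stress in WT, App −0.0035 and Tmem119 −0.0139 for stress in 5xFAD, and P2ry12 −0.0242 for the interaction. Non-myeloid marker covariate: 1 gene (Ms4a4a) higher for stress in 5xFAD, 626 lower for genotype under stress, 7 lists for stress in WT, App 0.13 and Fkbp5 −0.43 for genotype under stress, and App −0.0724 for stress in 5xFAD. Replicate block: 479 lower and Fkbp5 −0.15 for genotype under stress, and for the interaction Trem2 0.0201. Across 18 pairs of libraries with one replicate number the correlation was −0.525 to 0.511, above 0.1 in 3, so the block was kept as an alternative only. Lists: with an estimated correlation 0 passed in each of the 5 comparisons, and with fry 0 for stress in WT, stress in 5xFAD and the interaction. With fry 24 passed for genotype without stress and 20 for genotype under stress.

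Leaving out each library in turn gave these ranges, lowest to highest. Genotype without stress: 610 to 1452 lower, App −0.0507 to 0.1617, Fkbp5 −0.5512 to 0.0031. Genotype under stress: 1599 to 2488 higher, 564 to 2032 lower, App −0.3275 to 0.0198, Fkbp5 −0.1263 to 0.1995. Stress in WT: 8 to 21 lists, Fkbp5 −0.2983 to 0.2557. Stress in 5xFAD: 0 to 2 genes higher, App −0.0156 to 0.0763, P2ry12 −0.1374 to 0.0347, Tmem119 −0.136 to 0.2262. Interaction: 8 to 19 lists, Clec7a −0.1714 to 0.0773, Itgax −0.2038 to 0.1388, P2ry12 −0.0254 to 0.1572, Trem2 −0.1882 to 0.0712. The covariance of stress and genotype effects ran from −0.169 to −0.103 on leaving out a 5xFAD control library.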

Other observations

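The terms of the deposited annotation and the tests by sex in this part were chosen only after the result was seen. Of 2463 annotation terms of 15 to 300 genes, several name groups outside the lists above. In unstressed mice 32 of 60 proteasome complex genes rose in 5xFAD and 1 fell (median log2 0.30; fry adjusted p = 2.09e-05), as did 33 of 89 mitochondrial translation genes with 1 lower (0.31; fry adjusted p = 0.000149) and 21 of 47 translation initiation factor genes (0.28; fry adjusted p = 0.000309). In stressed mice the counts were 33, 39 and 22 (fry adjusted p = 1.30e-05, 5.47e-05 and 0.000146). Of all 16169 genes 2371 rose in unstressed and 2449 in stressed mice. The fry test does not set a group against other genes, and it also passed for 24 and 20 of the 34 lists. Its p-values therefore do not show that these terms stand out. Library totals alone shift the median of all genes by −0.17 and −0.18 log2 in these comparisons. Extracellular matrix genes fell in 40 of 189 cases in unstressed 5xFAD mice and rose in 14 (median −0.83; fry adjusted p = 0.114), and fell in 66 and rose in 14 under stress (median −0.97; fry adjusted p = 0.0404), beside the lower non-myeloid markers of these libraries.

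Xist-high and Y-high libraries differed as well. With the 4 groups in the model, limma called 941 of 16169 genes between the 6 Xist-high and the 8 Y-high libraries, and 897 of them are autosomal (568 higher and 329 lower in Xist-high). Within each group the Xist-high libraries carry the highest replicate numbers. Sex therefore cannot be told apart here from anything that follows the order of the samples, such as a batch. The immediate early gene Egr2 was at 7714 scaled counts on average in Xist-high and 3911 in Y-high libraries (log2 1.06; limma adjusted p = 0.000283), and Rgs1 (0.65), Cited2 (0.57) and Ncl (0.62) were higher as well. Of 25 immediate early genes 5 were higher (camera adjusted p = 0.000159), and of 24 inflammatory genes 7 (camera adjusted p = 0.000765), both with adjusted p = 0.827 with an estimated correlation. Of 13 astrocyte and 15 endothelial and mural markers 1 each was lower (medians −0.74 and −0.74; camera adjusted p = 0.000159 for each, and adjusted p = 0.827 with an estimated correlation), and both choroid-rich libraries were Y-high.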
